A study of Triticum aestivum with 6 samples.

How the data were processed

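Gene expression was measured by RNA-seq in roots of wheat (Triticum aestivum, line JW1) seedlings. Per the labels' protocols, seedlings germinated for 3 days, lost the endosperm, grew for 3 days with 2 mM nitrate and then for 2 days without nitrogen. They were then placed for 3 h in medium with 5 µM abscisic acid (ABA), a stress hormone, and either potassium chloride or 2 mM potassium nitrate. The labels give 6 samples in 2 groups of 3, named 0N+ABA for 0 mM nitrate and 2N+ABA for 2 mM nitrate. The series design also names both nitrate levels without ABA, and those groups were not analysed here. Each sample's group came from its title and treatment label. One further label of the samples names leaf tissue, while the tissue and source labels and the protocol name root, and root was used. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

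Libraries were poly(A)-selected, fragmented, primed with random hexamers, PCR-amplified and circularized, per the labels' protocols, which record no strand information or molecular identifiers. Counts of reads are therefore not counts of independent molecules. HISAT and Bowtie2 are named, without versions or roles, per the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here. The authors deposited one table with estimated counts per gene and sample, which were not normalized, together with TPM values, per the file headers. The authors also deposited FPKM values per gene and sample, per the file headers, and these were not used in any test. The estimated counts held whole numbers in 55.19% to 56.28% of values per sample, within a tolerance of 1e-06. The table lists 83219 genes, of which 78756 had a count in at least 1 sample. It pairs 82979 of the gene IDs with protein names from UniProt, and 18530 of the genes are named as uncharacterized. These names are matches to proteins of several plant species and not curated wheat gene names. Of the gene IDs, 0 matched the reference gene table of the IWGSC CS RefSeq v2.1 assembly that was at hand, so no coordinates are given and the chromosome and subgenome come from the gene ID. Another 2 columns with means of groups outside the 6 samples were not used.

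Library totals ran from 16907317 to 17735564 estimated counts. The counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and the quasi-likelihood test (glmQLFit and glmQLFTest), 2N+ABA against 0N+ABA, with no covariate. The filter kept 53862 genes, which held 99.61% of the counts. P-values were adjusted by Benjamini-Hochberg over these genes, and a gene was said to rise, fall or differ at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Expression levels are given as CPM, estimated counts normalised to library size with TMM factors by edgeR, as mean ± SD over the 3 samples of a group. A gene without any count in a group was given a lower bound on its fold, computed against 3 counts in each library. That floor is 0.174 CPM in 0N+ABA and covers counting error only.

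A total of 36 gene lists were fixed before the data were examined, as patterns of protein names for pathways of nitrogen, hormones, nutrients, cell wall, growth and stress, and for markers of other tissues and cell types. After the table was seen, but before any list statistic was computed, matching was limited to recommended and submitted names with the pattern at the start of a word, because some patterns had matched inside unrelated words. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, and 35 lists qualified. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list moved differently from all other genes, and fry whether its genes moved, on balance, one way. For each list the members that rose or fell are counted over all genes tested and, where the text says so, adjusted over the list alone. Members are also summarised by protein name. A planned test of annotation terms was not run, because the table used here pairs genes with protein names and not with terms. Protein names with 10 to 500 tested genes were tested in its place by a one-sided Fisher's exact test, a choice made after seeing the table.

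The rule for named genes was also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes that differed, had a mean of at least 1 CPM, groups that did not overlap and a described protein, with 1 gene per protein name. It added up to 4 members of each list with the smallest p, and the 3 genes with the largest share of counts. Wheat is hexaploid, and its A, B and D copies of a gene (homoeologs), like tandem copies, can be near-identical. How the counting divided reads among them is not given, so values of single copies are uncertain. Called genes per subgenome were compared by Fisher's exact test, which treats genes as independent.

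The count test was tested on simulated data drawn for the 53862 genes from the real means, dispersions and library sizes, with 200 genes changed. In that simulation of 2N+ABA against 0N+ABA, 97% of genes changed by 2 log2 units were called, against 30.3% at 1 and 2.94% at 0.5, and 10 of 96 calls were false. The adjusted threshold is stricter where few genes change, so these shares do not carry over to a comparison with more calls. Camera with the preset correlation called 5 of 5 simulated raised lists and 0 of 30 unchanged ones, and camera with an estimated correlation called 1 of 5 and 0 of 30. The simulated genes were independent of each other, so false list calls that arise from correlation between genes were not tested. Pairs of replicates were checked for holding the same library, and all differed by more than counting noise, with a chi-square per gene of 3.68 to 15.3. Alternatives were 2 other scalings, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (1 CPM in at least 3 samples and a mean of at least 50 counts), the replicate number as a block, leaving out each sample, and counts summed over protein names. Alternatives planned for a table without counts did not apply. Added after seeing the data were list counts by DESeq2 and limma-voom, limma on log2(TPM + 1), wider list patterns, list tests under the other scalings and filters, subgenome tests other than at 2-fold, protein name results at 2-fold, counts of list members without 0N+ABA replicate 2, and protein name results without each sample.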

Results

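RNA-seq libraries were collected from wheat roots after 3 h with 5 µM ABA, in 3 samples without nitrate (0N+ABA) and 3 samples with 2 mM nitrate (2N+ABA). The seedlings had spent the preceding 2 days without nitrogen, so the comparison asks which transcripts differ when nitrate is resupplied together with ABA. Potassium chloride took the place of potassium nitrate in 0N+ABA, so effects of nitrate and of chloride cannot be told apart. The libraries held 16940460, 17356813 and 16907317 estimated counts in 0N+ABA replicates 1, 2 and 3, and 17735564, 17269765 and 17657874 in the 2N+ABA replicates. The 10 most abundant genes took between 1.67% and 2.04% of the counts of a library. The 3 genes with the largest shares encoded the dehydrin COR410 (TraesCS6B02G273400, 0.221% of counts), a sucrose synthase (TraesCS7B02G063400, 0.217%) and the aquaporin TIP1-1 (TraesCS4B02G310900, 0.206%). None of these passed the test (adjusted p = 0.467, 0.844 and 0.14), though TIP1-1 passed without 0N+ABA replicate 2 (adjusted p = 0.0245).

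With nitrate, 25 of 29 genes for high-affinity nitrate uptake and 12 of 19 for nitrate and nitrite reduction rose, with median log2 fold changes of 5.38 and 2.08. For the supply of reductant 15 of 58 rose (median 0.06), and for ammonium assimilation 10 of 47 (median 0.15). None of the genes of these 4 lists fell by edgeR. All 4 lists passed camera at a preset correlation, and none passed with an estimated one (adjusted p = 0.229, 0.229, 0.341 and 0.229). A gene for NAR2.1, the partner protein of nitrate transporters (TraesCS4A02G367300), went from 4.71 ± 0.542 to 196 ± 62.7 CPM (SD, n = 3), and a nitrite reductase gene (TraesCS6B02G364600) from 14.5 ± 6.27 to 356 ± 90.0 CPM. Peroxidases, dehydrins and expansins also included more genes that rose than fell, while 8 of 46 trehalose metabolism genes and 14 of 424 histone and cyclin genes fell. Of 53862 genes tested, 1210 (2.25%) differed between the groups by edgeR's quasi-likelihood test. Of these, 898 were higher and 312 lower in 2N+ABA, and 708 differed by at least 2-fold, 564 of them upward. At an unadjusted p under 0.05 there were 8830 genes, and the groups did not overlap in 22.1% of the tested genes, where chance gives 10%.

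On the first principal component, which held 42.1% of the variance, 0N+ABA replicates 1 and 3 lay at -63.8 and -74.1 and the 2N+ABA libraries between 38.8 and 59.9. 0N+ABA replicate 2 lay between the groups at -1.28, and apart from all others on the second component at -79.0. The count of genes depended on which library was included. It was 4607 without 0N+ABA replicate 2, with 2852 higher and 1755 lower, and 1208 of the 1210 genes were among them. It was 425 without 0N+ABA replicate 1, 434 without 0N+ABA replicate 3, and 283, 539 and 423 without 2N+ABA replicates 1, 2 and 3. The genes that differed by at least 2-fold numbered 346, 1905, 358, 268, 463 and 370 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. DESeq2 called 2262 genes, and 1195 of the 1210 were among them.

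**Figure D1:**
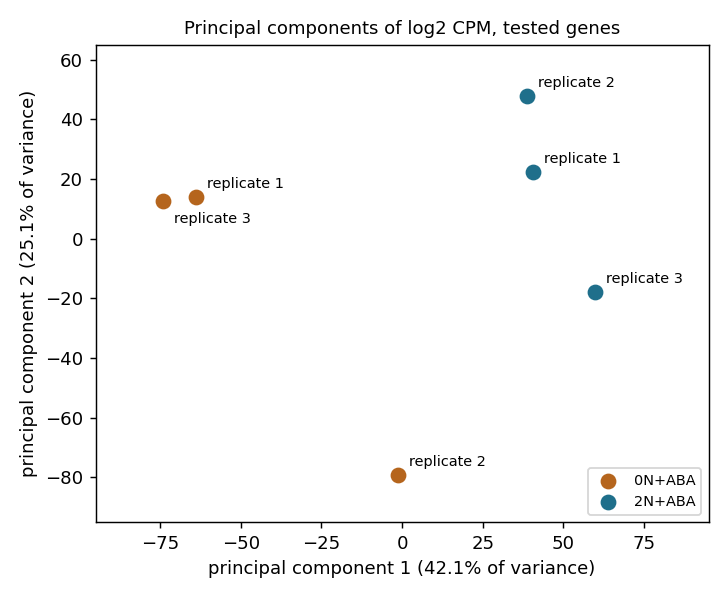
Positions of the 6 libraries on the first 2 principal components of log2 CPM over the tested genes, in arbitrary units, with 1 point per library and colour for the group. The 2N+ABA libraries lie at 38.8 to 59.9 on the first component, and 0N+ABA replicate 2 lies apart from the other 0N+ABA libraries at -79.0 on the second.

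The high-affinity nitrate uptake list had the largest median change of all lists. Of its 29 tested members, 25 rose and 0 fell by edgeR (0 by DESeq2 and limma-voom, and 0 at an unadjusted p under 0.05), with a median log2 fold change of 5.38, and 26 rose when adjusted over the list alone. All 15 genes matched to the high-affinity nitrate transporter NRT2.1, which carries nitrate at low external concentrations, rose. One of them, TraesCS6D02G035700 on chromosome 6D, had no count in any 0N+ABA library and 11.7 ± 6.27 CPM in 2N+ABA, at least 67.3-fold higher against a floor of 3 counts per library (adjusted p = 0.0118, and adjusted p = 0.059 without 2N+ABA replicate 1). In all, 2 members had no count in 0N+ABA, and the list median was also 5.38 with these at their lower bounds. All 6 genes for NAR2.1, which NRT2 transporters need, rose as well, by log2 fold changes between 2.21 and 5.38, the largest in TraesCS4A02G367300 (SE 0.282, adjusted p = 9.44e-05). Camera placed the list above other genes (adjusted p = 8.37e-45), with adjusted p = 0.229 with an estimated correlation.

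Among 191 transporters of the larger NRT1/PTR family, 7 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone. Of the 7, 6 were matched to NPF6.3, a nitrate transporter and sensor of which 9 genes were tested. TraesCS1A02G210900 rose from 0.253 ± 0.240 to 16.7 ± 3.58 CPM and TraesCS1B02G224900 from 0.290 ± 0.106 to 17.5 ± 2.27 CPM (adjusted p = 0.000218 and 3.87e-05). The rises numbered 14 without 0N+ABA replicate 2, and the falls 0, 3, 2, 0, 0 and 1 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. The family as a whole did not pass camera (adjusted p = 0.485), which pointed downward like the median log2 fold change of -0.04, while the mean was 0.04. The NRT2.1 and NPF6.3 genes include groups of similar copies, so the division of reads among copies is uncertain.

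Enzymes that reduce nitrate to ammonium were higher with nitrate as a list. Of 19 tested genes, 12 rose and 0 fell by edgeR (0 falls by DESeq2 and limma-voom, and 0 lower at an unadjusted p under 0.05), and 13 rose when adjusted over the list alone, with a median log2 fold change of 2.08 (camera adjusted p = 5.18e-17, and adjusted p = 0.229 with an estimated correlation). They were 6 of 7 nitrate reductase genes, 3 of 3 ferredoxin-dependent nitrite reductase genes, and 3 of 3 genes for uroporphyrinogen-III C-methyltransferase, which makes the siroheme cofactor of nitrite reductase. The nitrate reductase gene TraesCS6A02G326200 rose from 4.20 ± 1.31 to 101 ± 39.4 CPM (log2 fold change 4.58, SE 0.344, adjusted p = 0.000535). The nitrite reductase gene TraesCS6B02G364600 rose by a log2 fold change of 4.62 (SE 0.337, adjusted p = 0.000458), and the methyltransferase gene TraesCS3D02G225500 went from 2.14 ± 0.0661 to 37.5 ± 7.98 CPM (adjusted p = 6.55e-05).

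Non-symbiotic hemoglobins, which scavenge nitric oxide, gave 3 rises and 0 falls among 9 tested genes by edgeR (0 falls by DESeq2 and limma-voom, and 0 at an unadjusted p under 0.05), and 5 rises when adjusted over the list alone. TraesCS1A02G338400 rose from 0.193 ± 0.0315 to 14.6 ± 1.22 CPM, TraesCS1B02G350800 from 0.885 ± 0.482 to 54.1 ± 9.32 CPM, and TraesCS1D02G340600 from 1.93 ± 0.173 to 59.1 ± 10.2 CPM (adjusted p = 2.84e-05, 8.18e-05 and 3.24e-05). The list median in 0N+ABA replicate 2 was -1.80 relative to the gene means, against -0.23 and -0.32 in the other 0N+ABA libraries, and 5 genes rose without that library. Camera gave the list an adjusted p of 2.65e-06, and adjusted p = 0.243 with an estimated correlation.

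**Figure D2:**
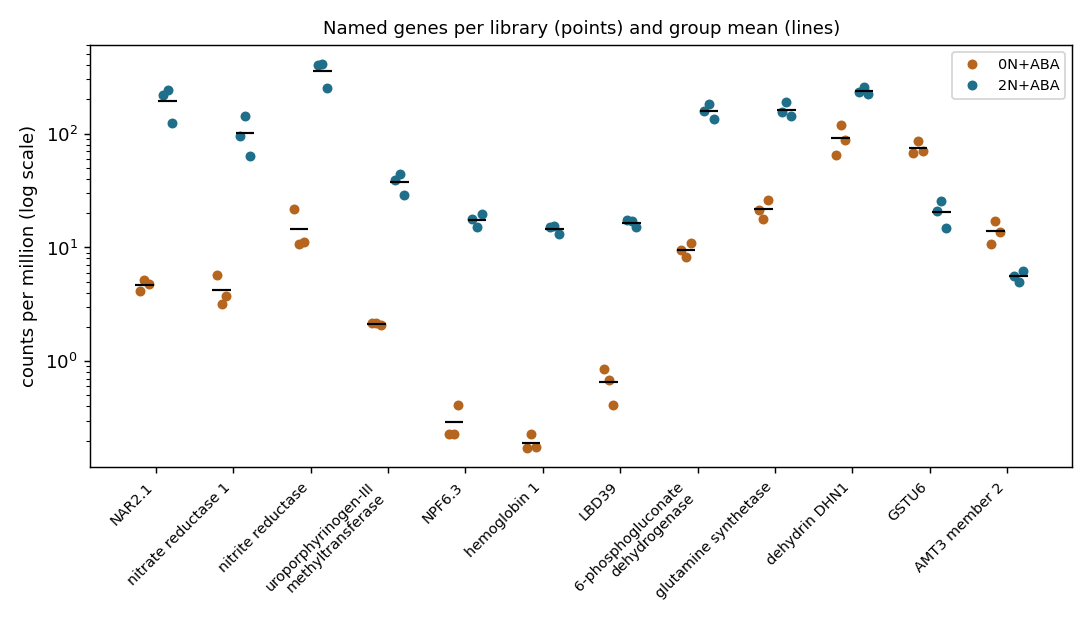
CPM on a log scale for 12 named genes, with 1 point per library, colour for the group and a line at the mean of 3 libraries. NAR2.1 (TraesCS4A02G367300) lies at a mean of 4.71 CPM in 0N+ABA and 196 CPM in 2N+ABA, and the glutathione S-transferase GSTU6 (TraesCS6A02G139100) at 74.6 and 20.5 CPM.

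Some plastid enzymes that supply reductant for these steps were among the genes that rose. Of 58 tested genes, 15 rose and 0 fell by edgeR, and 17 rose and 2 fell when adjusted over the list alone. At an unadjusted p under 0.05, 3 were lower, and DESeq2 and limma-voom called 0 falls. The 15 were 3 of 3 genes each for 6-phosphogluconate dehydrogenase 2, glucose-6-phosphate dehydrogenase 2 and root ferredoxin-NADP reductase, 3 of 4 for ferredoxin-6, and 3 transketolase genes. The 6-phosphogluconate dehydrogenase gene TraesCS1D02G361400 went from 9.54 ± 1.30 to 159 ± 22.5 CPM (log2 fold change 4.06, SE 0.164, adjusted p = 3.87e-05), and the glucose-6-phosphate dehydrogenase gene TraesCS2A02G067800 rose by a log2 fold change of 3.09 (SE 0.132, adjusted p = 5.13e-05). The list median was 0.06. One member fell without 0N+ABA replicate 2. Camera gave an adjusted p of 6.35e-07, and adjusted p = 0.341 with an estimated correlation.

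Among 47 ammonium assimilation genes, 10 rose and 0 fell by edgeR (0 falls by DESeq2 and limma-voom, and 1 gene lower at an unadjusted p under 0.05), and 14 rose when adjusted over the list alone. Those that rose were 3 of 3 plastid glutamine synthetase genes, 3 of 3 genes of a cytosolic isozyme, 3 of 3 ferredoxin-dependent glutamate synthase genes and 1 asparagine synthetase gene. TraesCS2A02G500400, a plastid glutamine synthetase, went from 21.8 ± 4.31 to 162 ± 23.7 CPM and TraesCS2B02G152900, a glutamate synthase, from 34.8 ± 3.02 to 105 ± 13.2 CPM (adjusted p = 0.000194 and 0.000779). The list had a camera adjusted p of 9.11e-06, and adjusted p = 0.229 with an estimated correlation, and 17 members rose without 0N+ABA replicate 2. Of 78 genes for carbon skeletons, 10 rose and 0 fell by edgeR (0 falls by DESeq2 and limma-voom, and 1 gene lower at an unadjusted p under 0.05), and 17 rose when adjusted over the list alone. Among them were the phosphoenolpyruvate carboxylase gene TraesCS7B02G237900 (log2 fold change 1.66, SE 0.130) and the aconitase genes TraesCS6B02G440200 and TraesCS6D02G384200 (0.88 each), whose calls were lost without 2N+ABA replicate 1 (adjusted p = 0.0518 and 0.0627). The 10 rises were 6, 14, 6, 2, 4 and 6 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. Camera gave this list an adjusted p of 5.34e-07, and adjusted p = 0.3 with an estimated correlation.

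Regulators of the nitrate response went both ways, with 8 rises and 6 falls among 61 genes, and 12 and 10 when adjusted over the list alone. All 3 genes for LBD39, a repressor of nitrogen-responsive genes, rose by 3.79 to 4.64 on the log2 scale, led by TraesCS4A02G236200, which went from 0.653 ± 0.226 to 16.5 ± 1.14 CPM (adjusted p = 5.73e-05). NLP proteins are transcription factors of the nitrate response. The NLP3 gene TraesCS6B02G130800 rose from 1.46 ± 0.272 to 7.13 ± 0.136 CPM (adjusted p = 0.000535), while 4 of 8 genes for NLP1 fell. The 8 rises were 5, 11, 6, 5, 6 and 5, and the 6 falls 2, 12, 3, 0, 2 and 2, without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. Camera did not place the list apart from other genes (adjusted p = 0.471), pointing upward like the mean log2 fold change of 0.25, while the median was -0.05.

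Of 12 ammonium transporter genes, 0 rose and 2 fell by edgeR, both matched to ammonium transporter 3 member 2, and 2 rose and 3 fell when adjusted over the list alone. DESeq2 called 1 rise, limma-voom 0, and 2 genes were higher at an unadjusted p under 0.05. TraesCS5D02G519400 fell from 13.9 ± 3.17 to 5.62 ± 0.658 CPM (adjusted p = 0.0126) and TraesCS5B02G520200 from 5.91 ± 1.34 to 2.84 ± 0.385 CPM (adjusted p = 0.0391). The falls numbered 1, 3, 0, 0, 0 and 1 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, and 3 genes rose without 0N+ABA replicate 2. The list did not pass camera (adjusted p = 0.448). Among 129 amino acid transporters, 12 rose and 1 fell, and 15 rose and 8 fell when adjusted over the list alone. Of the 12, 6 were matched to the vacuolar transporter AVT6A, led by TraesCS7A02G391600 (log2 fold change 1.39, SE 0.108, adjusted p = 0.000652). In the same order of libraries left out, 5, 22, 7, 5, 7 and 8 of these transporters rose and 0, 11, 0, 0, 1 and 0 fell. That list did not pass camera (adjusted p = 0.552), which pointed upward while its median and mean were -0.04 and -0.01.

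LEA proteins and dehydrins, which accumulate under water deficit and ABA, included many genes that were higher with nitrate, with ABA present in both groups. Of 108 tested genes, 29 rose and 0 fell by edgeR, with a median log2 fold change of 0.62, and 64 rose and 3 fell when adjusted over the list alone. At an unadjusted p under 0.05, 4 were lower, and DESeq2 and limma-voom called 0 falls. The 29 included 8 of 11 genes for dehydrin DHN3, with log2 fold changes between 1.14 and 1.67. TraesCS6D02G333100, a DHN3 gene, went from 19.6 ± 4.02 to 50.9 ± 8.15 CPM (log2 fold change 1.38, SE 0.175, adjusted p = 0.00779). TraesCS5A02G369900, a DHN1 gene, went from 90.8 ± 26.6 to 237 ± 16.3 CPM (adjusted p = 0.0138), and its call was lost without 0N+ABA replicate 3 or 2N+ABA replicates 1, 2 or 3 (adjusted p = 0.067, 0.0744, 0.0523 and 0.0505). The 29 rises were 3, 67, 1, 5, 6 and 5 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, and 1 gene fell without 0N+ABA replicate 2. The list median in that library was -0.04 relative to the gene means, against -0.51 and -0.46 in the other 0N+ABA libraries and 0.17 to 0.56 in 2N+ABA. Camera placed the list above other genes (adjusted p = 6.81e-20), but it did not pass with an estimated correlation or by fry (adjusted p = 0.341 and 0.0931). Endodermis markers, with a median log2 fold change of 0.30 (camera adjusted p = 0.000438, and 0.523 with an estimated correlation), had library medians of 0.25 in 0N+ABA replicate 2, -0.42 in each other 0N+ABA library and 0.04 to 0.28 in 2N+ABA. This marker list was matched by protein name and included CASP-like proteins, whose restriction to the endodermis was not tested.

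In the core ABA signalling list, 2 of 90 genes rose and 1 fell, also when adjusted over the list alone. The 3 genes encode SnRK2 kinases, of which the SAPK3 genes TraesCS1D02G218200 and TraesCS1B02G229400 rose by log2 fold changes of 0.58 and 0.64 and the SAPK2 gene TraesCS2A02G163800 fell by 0.79 (adjusted p = 0.0318, 0.0444 and 0.049). Without 0N+ABA replicate 2, 12 members rose and 7 fell, and 0 rose or fell by edgeR without 0N+ABA replicates 1 or 3 or 2N+ABA replicates 1, 2 or 3. That list did not pass camera (adjusted p = 0.418). Of 17 ABA metabolism genes, 0 were called by edgeR and limma-voom, DESeq2 called 2 falls, 4 were lower at an unadjusted p under 0.05, and 3 fell when adjusted over the list alone (camera adjusted p = 0.471). One of these fell without 0N+ABA replicate 2. The ABA synthesis gene NCED3 on chromosome 5B, TraesCS5B02G375900, had a log2 fold change of -0.99 (SE 0.257, adjusted p = 0.0961).

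Of 431 class III peroxidases, enzymes that act on cell walls and hydrogen peroxide, 60 rose and 6 fell, and 133 rose and 17 fell when adjusted over the list alone. The rises included 25 of 101 genes matched to peroxidase 2 and 21 of 84 matched to peroxidase 1. TraesCS7B02G298500, a peroxidase 2 gene, went from 3.51 ± 0.234 to 15.1 ± 3.68 CPM and TraesCS1D02G317800, a peroxidase 1 gene, from 15.2 ± 2.70 to 60.6 ± 13.3 CPM (adjusted p = 0.0019 and 0.00207). Of 231 expansins and xyloglucan enzymes, which remodel cell walls, 17 rose and 1 fell, and 46 rose and 4 fell when adjusted over the list alone. TraesCS6A02G217100, matched to expansin-B7, rose by a log2 fold change of 3.16 (SE 0.231, adjusted p = 0.000458), and 5 of 15 genes for expansin-B6 rose. Of 84 aquaporins, which are water channels, 2 rose and 0 fell by edgeR, and 18 rose and 1 fell when adjusted over the list alone. DESeq2 called 1 aquaporin fall, limma-voom 0, and 2 aquaporins were lower at an unadjusted p under 0.05. Both that rose were PIP2-6 genes, at log2 fold changes of 0.92 (TraesCS5D02G112500, adjusted p = 0.00429) and 1.04 (TraesCS5A02G100000, adjusted p = 0.00779, and 0.0581 without 2N+ABA replicate 1).

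Camera adjusted p was 2.13e-09 for peroxidases, 4.23e-12 for expansins and xyloglucan enzymes and 2.39e-07 for aquaporins, all upward, and with an estimated correlation the adjusted p was 0.243, 0.256 and 0.523. The 60 peroxidase rises were 27, 131, 27, 16, 48 and 19, and the 6 falls 3, 35, 3, 0, 2 and 1, without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. In the same order the 17 rises of expansins and xyloglucan enzymes were 2, 57, 3, 1, 16 and 2 and the single fall 0, 3, 0, 0, 2 and 0, and the 2 aquaporin rises were 2, 26, 2, 1, 2 and 2. One aquaporin fell without 0N+ABA replicate 2. The aquaporin median in that library was 0.13 relative to the gene means, against -0.30 and -0.23 in the other 0N+ABA libraries and 0.07 to 0.22 in 2N+ABA. The endodermis marker medians were 0.25 in that library, -0.42 in each of the other 0N+ABA libraries and 0.04 to 0.28 in 2N+ABA.

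Replication histones and mitotic cyclins, transcripts of dividing cells, passed camera downward at the preset correlation, but neither with an estimated correlation nor by fry (adjusted p = 0.341 and 0.107). Of 424 tested genes, 0 rose and 14 fell by edgeR (0 rises by DESeq2 and limma-voom, and 0 higher at an unadjusted p under 0.05), and 72 fell when adjusted over the list alone. The median log2 fold change was -0.31 (camera adjusted p = 6.87e-22). The falls included 3 of 19 genes matched to histone H2B.3 and 1 gene for cyclin A3-2. The H2B.3 gene TraesCS7D02G485700 went from 5.31 ± 0.918 to 2.16 ± 0.323 CPM (adjusted p = 0.0165), and its call was lost without 0N+ABA replicates 1 or 3 or 2N+ABA replicates 1 or 3 (adjusted p = 0.0664, 0.0653, 0.0941 and 0.0752). The 14 falls were 0, 52, 1, 0, 2 and 0 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. Endodermis markers, taken by protein name to come from differentiated cells, had a median of 0.30, in the other direction. Camera gave that list an adjusted p of 0.000438, and 0.523 with an estimated correlation. Of the endodermis markers, 0 were called by edgeR, DESeq2 and limma-voom, and 2 had an unadjusted p under 0.05. Without 0N+ABA replicate 2, 12 endodermis and 17 xylem markers rose and 4 xylem markers fell, as calls over all genes went from 1210 to 4607. Of 453 cytosolic ribosomal protein genes, 0 were called by edgeR, DESeq2 and limma-voom, 0 passed when adjusted over the list alone, and 21 had an unadjusted p under 0.05. Their median log2 fold change was -0.08 (camera adjusted p = 0.00124, and adjusted p = 0.678 with an estimated correlation), and camera's call was lost without 0N+ABA replicate 1 (adjusted p = 0.142). One of these genes rose without 0N+ABA replicate 2.

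In trehalose metabolism, 1 of 46 genes rose and 8 fell, and 1 rose and 13 fell when adjusted over the list alone. Of the falls, 4 were matched to the trehalose 6-phosphate phosphatase RA3, which removes the phosphate of the sugar signal trehalose 6-phosphate. TraesCS2B02G187200 fell from 53.2 ± 5.34 to 22.9 ± 1.61 CPM (log2 fold change -1.22, SE 0.116, adjusted p = 0.0019). Camera adjusted p for this list was 7.53e-05, and adjusted p = 0.341 with an estimated correlation. The 8 falls were 2, 19, 2, 1, 4 and 2, and the single rise 0, 2, 0, 0, 1 and 1, without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn.

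**Figure D3:**
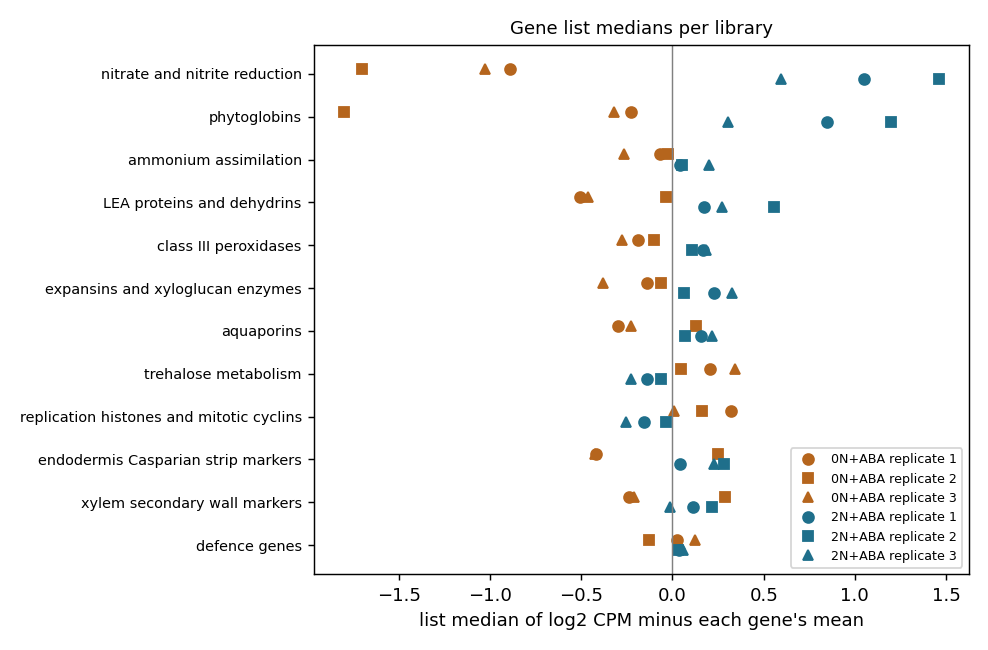
Median over the tested members of 12 gene lists of log2 CPM minus each gene's mean over the 6 libraries, with 1 symbol per library, colour for the group and shape for the replicate. For LEA proteins and dehydrins, 0N+ABA replicate 2 lies at -0.04 between the other 0N+ABA libraries (-0.51 and -0.46) and the 2N+ABA libraries (0.17 to 0.56).

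Among 78 cytokinin genes, 3 rose and 2 fell, and 5 rose and 15 fell when adjusted over the list alone. An isopentenyltransferase gene, TraesCS5D02G471100, which makes cytokinin, rose (log2 fold change 2.24, SE 0.374, adjusted p = 0.0239), as did 2 cytokinin dehydrogenase genes, which degrade it. The list leaned downward (median -0.28, camera adjusted p = 0.0025), but camera's call was lost without a filter (adjusted p = 0.338) and with an estimated correlation (adjusted p = 0.243). Among 191 auxin genes, 1 rose and 2 fell, also when adjusted over the list alone, and the falls were the IAA2 gene TraesCS3D02G110200 and the ARF16 gene TraesCS7A02G160800 (log2 fold changes -0.84 and -0.76, adjusted p = 0.0183 and 0.0212). Camera gave the auxin list an adjusted p of 0.0412, and adjusted p = 0.341 with an estimated correlation. Its call was lost without 0N+ABA replicates 2 or 3 or 2N+ABA replicates 1 or 2 (adjusted p = 0.189, 0.0831, 0.149 and 0.0977). It was also lost without a filter, with the replicate number as a block and with wider name patterns (adjusted p = 0.255, 0.052 and 0.0526). Without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, the cytokinin rises were 1, 5, 0, 0, 0 and 0 and the falls 0, 13, 0, 0, 1 and 0, and the auxin rises were 1, 1, 0, 0, 0 and 0 and the falls 1, 14, 0, 0, 0 and 0.

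Of 63 ethylene biosynthesis genes, 3 rose and 0 fell by edgeR (0 falls by DESeq2 and limma-voom, and 6 genes lower at an unadjusted p under 0.05), and 5 rose and 1 fell when adjusted over the list alone. All 3 were matched to ACC oxidase, which makes ethylene, led by TraesCS4D02G095500 from 7.61 ± 1.33 to 20.1 ± 1.46 CPM (adjusted p = 0.00277). The list did not pass camera (adjusted p = 0.906), and its median of -0.03 and mean of 0.01 differ in sign. Without 0N+ABA replicate 2, 8 members rose and 3 fell. Of 26 gibberellin genes, 0 were called by edgeR, DESeq2 and limma-voom, 0 passed when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Their median was -0.26 (camera adjusted p = 0.00911, and adjusted p = 0.243 with an estimated correlation). Camera's call was lost without 0N+ABA replicate 1, with the stricter filter and with wider name patterns (adjusted p = 0.0773, 0.105 and 0.116), and 2 of these genes fell without 0N+ABA replicate 2.

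Among 81 sulfate genes, 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. The rises included 4 cysteine synthase genes such as TraesCS7D02G096800 (log2 fold change 1.36, SE 0.147, adjusted p = 0.00344). The sulfate rises numbered 2, 8, 2, 1, 2 and 2, and the falls 0, 2, 1, 0, 2 and 0, without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, and the list did not pass camera (adjusted p = 0.167), but passed with wider name patterns and passed fry (adjusted p = 0.0494 and 0.038). Of 132 phosphate genes, 2 transporter genes rose and 2 glycerophosphodiester phosphodiesterase genes fell, and 3 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.887). In the same order of libraries left out, 1, 6, 1, 1, 1 and 1 of them rose and 0, 6, 0, 0, 0 and 1 fell. Of 68 iron uptake genes, 2 rose and 2 fell, and 2 rose and 10 fell when adjusted over the list alone. The yellow stripe 1 gene TraesCS1B02G445700, for a transporter of iron bound to phytosiderophores, rose from 2.91 ± 0.192 to 8.47 ± 1.13 CPM (adjusted p = 0.00241), and 2 of 9 genes for the transporter YSL12 fell. Camera gave the iron list an adjusted p of 0.0339 downward, and adjusted p = 0.341 with an estimated correlation. That call was lost without 0N+ABA replicates 2 or 3 or 2N+ABA replicate 2 (adjusted p = 0.402, 0.0671 and 0.0654), and without a filter or with the stricter filter (adjusted p = 0.295 and 0.199). In the same order as above 1, 4, 1, 1, 1 and 1 iron genes rose and 0, 8, 0, 1, 0 and 1 fell.

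Of 44 glutaredoxins, 0 were called by edgeR and limma-voom, 0 passed when adjusted over the list alone, DESeq2 called 1 fall, 5 had an unadjusted p under 0.05, and 1 fell without 0N+ABA replicate 2 (camera adjusted p = 0.452). Of 120 heat shock protein genes, 3 rose and 0 fell by edgeR, and 7 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.303). DESeq2 called 3 heat shock falls, limma-voom 0, and 6 genes were lower at an unadjusted p under 0.05. The 3 heat shock rises were 0, 12, 0, 1, 0 and 0 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, with 5 falls without 0N+ABA replicate 2. Among 430 defence genes, 18 rose and 2 fell, and 36 rose and 10 fell when adjusted over the list alone. Of the 18, 4 were matched to WRKY transcription factor 19, among them TraesCS2D02G525000, TraesCS2A02G523100 and TraesCS2B02G552800 (log2 fold changes 2.21, 1.76 and 1.95). In the same order, 9, 37, 7, 7, 11 and 9 defence genes rose and 1, 37, 0, 0, 1 and 0 fell. The defence list had a camera adjusted p of 0.393, pointing upward while its median and mean were -0.01 and -0.05, and it passed without 0N+ABA replicate 3 (adjusted p = 0.0431). The list of CLE and CEP signalling peptides held 2 tested genes, which are named as KDEL-tailed endopeptidases and not peptides, and was too small for the list test. Neither gene passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05.

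Markers of other tissues and cell types were also tested. Of 101 photosynthetic shoot markers, 0 rose and 1 fell by edgeR, 0 passed when adjusted over the list alone, DESeq2 called 2 falls and 0 rises, limma-voom called 0, and 15 had an unadjusted p under 0.05. The fall, in the chlorophyll-binding protein gene TraesCS5B02G322900 (log2 fold change -0.95, adjusted p = 0.049), was lost without each library other than 0N+ABA replicate 2 (adjusted p between 0.11 and 0.154). The falls were 0, 3, 0, 0, 0 and 0 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn. The list's median log2 fold change was -0.25 (camera adjusted p = 0.00993, and adjusted p = 0.719 with an estimated correlation). Camera's call was lost without 0N+ABA replicate 3 or 2N+ABA replicates 2 or 3 (adjusted p = 0.372, 0.0715 and 0.893), and with the stricter filter (adjusted p = 0.246). Of 23 endodermis markers, 0 were called by edgeR, DESeq2 and limma-voom, 0 passed when adjusted over the list alone, and 2 had an unadjusted p under 0.05, with a median of 0.30 (camera adjusted p = 0.000438, and adjusted p = 0.523 with an estimated correlation). The endodermis median in 0N+ABA replicate 2 was 0.25 relative to the gene means, against -0.42 in each of the other 0N+ABA libraries and 0.04 to 0.28 in 2N+ABA.

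Of 63 xylem markers, 0 were called by edgeR and limma-voom, DESeq2 called 1 rise, and 6 had an unadjusted p under 0.05, with camera adjusted p = 0.0929. Xylem markers passed camera without 0N+ABA replicate 2 or 2N+ABA replicate 3, and with the replicate number as a block (adjusted p = 0.000876, 0.0175 and 0.0453). Of 7 root hair markers, 0 were called by edgeR and limma-voom, DESeq2 called 2 rises, and 3 had an unadjusted p under 0.05 and rose when adjusted over the list alone, with camera adjusted p = 0.0623. These 3 were all matched to ROOT HAIR DEFECTIVE 3 homolog 2, on chromosomes 6A, 6B and 6D, and may be copies of 1 gene. They are root hair markers by protein name only, and whether they mark root hair cells was not tested. The root hair list passed camera without 2N+ABA replicate 1 and with the block, and passed fry (adjusted p = 0.045, 0.026 and 0.038). Of 7 endosperm storage markers, 0 were called by edgeR, DESeq2 and limma-voom and 0 had an unadjusted p under 0.05, and of 19 phloem markers, 0 were called by the same tools and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.171 and 0.747). The median and mean of the phloem list, 0.02 and -0.03, differ in sign. For xylem, endosperm and phloem, 0 passed when adjusted over the list alone. Without 0N+ABA replicate 2, 12 endodermis, 17 xylem and 3 root hair markers rose, and 4 xylem markers fell. Of the 35 lists tested, 19 passed camera, 11 of them upward and 8 downward, and 0 passed with an estimated correlation. Fry passed 10 lists, 8 of them among the 19, and the other 2 were the sulfate and root hair lists. The 11 that passed camera but not fry were LEA proteins (fry adjusted p = 0.0931), auxin (0.131), gibberellin (0.0931), iron uptake (0.0952), expansins (0.0556), aquaporins (0.204), trehalose (0.0952), ribosomal proteins (0.204), histones and cyclins (0.107), photosynthetic markers (0.551) and endodermis markers (0.284). The other 2 scalings gave 0 opposite calls among these lists and 0 opposite signs among the 1210 genes. That shows little, because they moved log2 fold changes by medians of only 0.0041 and -0.016.

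Other large rises were in a gene for the zinc finger protein ZAT12 (TraesCS1B02G053000), with no count in any 0N+ABA library and 2.12 ± 0.572 CPM in 2N+ABA (at least 12.2-fold higher, adjusted p = 0.0054), a chloroplast carbonic anhydrase gene (TraesCS7A02G454400, log2 fold change 5.15, SE 0.300) and a gene for a tyrosine-sulfated glycopeptide receptor (TraesCS7A02G435000, 4.58, SE 0.284). A gene for a WAT1-related transporter fell from 5.09 ± 0.0765 to 1.10 ± 0.171 CPM (TraesCS6D02G308700, adjusted p = 0.000804). More abundant transcripts that fell were those of an early light-inducible protein (TraesCS5B02G218200, from 38.9 ± 12.8 to 10.1 ± 2.30 CPM), the glutathione S-transferase GSTU6 (TraesCS6A02G139100, from 74.6 ± 10.4 to 20.5 ± 5.50 CPM) and a cytochrome P450 of family 81 (TraesCS5D02G407500, from 85.8 ± 13.2 to 25.1 ± 5.69 CPM), with adjusted p of 0.00812, 0.00349 and 0.00267. Glutathione S-transferases conjugate glutathione to toxic compounds. Each of these 7 genes was called without any 1 of the 6 libraries. The largest fall among the named genes was in an aldo-keto reductase gene (TraesCS6D02G127900, log2 fold change -2.56, SE 0.458, adjusted p = 0.0299), whose call was lost without 0N+ABA replicate 1 or 2N+ABA replicates 1, 2 or 3 (adjusted p = 0.0876, 0.142, 0.0723 and 0.123).

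Calls were spread over the 3 subgenomes. In the A, B and D subgenomes, 381 of 17517 (2.18%), 363 of 17718 (2.05%) and 454 of 18005 (2.52%) tested genes differed (Fisher's exact test, two-sided, p = 0.00813). Among genes that differed by at least 2-fold (225, 215 and 259), Fisher's exact test gave p = 0.163. The exact p was 0.108, 0.0173, 0.738, 0.693, 0.258 and 0.39 without 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, and 0.0748 with genes called by DESeq2, so the difference in shares passed without 0N+ABA replicate 2 and was lost without each of the other 5 libraries.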

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

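The tests on log2(TPM + 1), the list tests under other scalings, filters and wider patterns, and the subgenome tests other than at least 2-fold were chosen after the result was seen. DESeq2's size factors (1201 genes), upper-quartile scaling (1216), no filter (1609), the stricter filter (1014), limma-voom (1108) and log2(TPM + 1) (889) gave counts within 1.5 times of 1210, and none of the 1210 genes had the opposite sign under any alternative that tested it. DESeq2 called 2262 genes (1519 higher, 743 lower, 1128 at least 2-fold), log2(TPM + 1) gave 424 at least 2-fold, and the causes were not tested. Deviations from the group means of equal replicate numbers correlated at 0.0757, -0.229 and -0.217 across genes, which are not independent replicates. The highest value of any pair was 0.343, for 0N+ABA replicate 2 with 2N+ABA replicate 3. With 3 samples per group, these values cannot settle whether replicate numbers pair the samples. With the replicate number as a block 723 genes differed (588 higher, 135 lower), 587 of the 1210 among them. Leaving out 1 library gave 283 to 4607 genes, 251 to 2852 higher, 32 to 1755 lower and 268 to 1905 at least 2-fold, with the highest counts without 0N+ABA replicate 2, and the other counts were lower with fewer samples. Summed over protein names, 251 of 10266 names differed, a count of fewer features. Of 35 lists, 19 passed camera, 16 to 20 under scalings, filters, the block, wider patterns and each library left out, 10 passed fry, 8 of them among the 19, and 0 passed with an estimated correlation, and the causes were not tested. Fisher's exact test of subgenomes gave p = 0.163 at 2-fold, 0.432 with the block, 0.0748 by DESeq2, 0.114 on log2(TPM + 1) and 0.0173 to 0.738 with 1 library left out, and the cause was not tested. Of 161 named genes, 0 reversed. Calls were lost in 26 with the block, 10 with limma-voom, 13 with log2(TPM + 1) and 34 to 48 without any library other than 0N+ABA replicate 2, without which 0 were lost and 25 gained. The annotation-term alternative was not run, nor were the pseudocount and mean-filter alternatives, which apply to tables without counts. In simulation, 2.94% of genes with a log2 change of 0.5 were called, but that simulation held only 96 calls in all. The adjusted threshold is stricter with few calls, so this share does not carry over to the 1210 calls here. How many small changes were missed at this depth and number of samples was not tested.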

Other observations

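The tests of protein names, of a wrong label, of differentiated tissue, of single libraries and of scaling were chosen after the result was seen. The low-oxygen test was chosen after 0N+ABA replicate 2 was seen to stand apart, but before the values of its list were seen, and the counts over other splits were planned before. Among 488 protein names with 10 to 500 tested genes, 13 were enriched among genes that fell and 12 among genes that rose. This exact test treats genes of a name as independent, though copies can share reads and vary together, so its p-values are likely too small. The smallest p among falls was for the glutathione S-transferase GSTU6, with 17 of 74 genes (Fisher's exact test, one-sided, adjusted p = 8.35e-19), and glutathione S-transferase 4 followed with 7 of 17 (adjusted p = 3.04e-09). These enzymes conjugate glutathione to toxic compounds. Falls were also enriched for the early light-inducible protein HV90 with 4 of 11 genes, for SRG1 with 4 of 11 and for ABC transporter G family member 36 with 4 of 18 (adjusted p = 8.53e-05, 8.53e-05 and 0.000609). Leaving out 0N+ABA replicates 1, 2 and 3 and 2N+ABA replicates 1, 2 and 3 in turn, 8, 8, 5, 5, 6 and 7 of the 13 names stayed enriched, 3 of them each time. GSTU6 and HV90 were among the 3. Glutathione S-transferase 4 was lost without 0N+ABA replicate 3 or any 2N+ABA library (adjusted p of at least 0.865), SRG1 without 2N+ABA replicate 1 (adjusted p = 0.661), and the ABC transporter without 0N+ABA replicates 2 or 3 or 2N+ABA replicates 1 or 2 (adjusted p of at least 0.0529). Among genes that fell at least 2-fold, 5 of the 13 names stayed enriched, and glutathione S-transferase 4 did not.

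Rises were enriched for the zinc finger protein ZAT12 (7 of 12 genes), thiosulfate sulfurtransferase 18 (6 of 10) and dormancy-associated protein homolog 3 (6 of 12), with adjusted p of 6.7e-08, 7.91e-07 and 2.89e-06 by the same exact test. In the same order of libraries left out, 8, 11, 8, 7, 9 and 8 of the 12 names stayed enriched, 7 of them each time. ZAT12 and the sulfurtransferase were among the 7, and the dormancy-associated protein was lost without 2N+ABA replicate 1 (adjusted p = 0.108). Among genes that rose at least 2-fold, 10 of the 12 stayed enriched. Among 5707 putative sets of A, B and D copies, 205 held a called gene, 122 of them only 1. Of the 37 sets with 2 calls and the 46 with 3, 0 held calls of opposite sign. The 3 copies had the same sign of change in 56.4% of sets, against a mean of 25.1% and a highest value of 26.9% in 1000 shuffles. The shuffles broke up the copies of a set. Any variation that copies share, from shared reads or from single libraries, also raises the share, so it cannot be assigned to nitrate.

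0N+ABA replicate 2 stood apart from its group, with 921 of 48519 genes at least 2-fold below both other 0N+ABA libraries and 343 above, against 39 to 286 below and 45 to 187 above in the other libraries. The commonest described protein names among the 921 were early nodulin-93 (31 of 36 genes), pathogenesis-related protein 1 (16 of 32) and subtilisin-like protease SBT3.9 (13 of 16). Pathogenesis-related protein PRB1-3 (9 of 13) had a median of -2.46 relative to the gene means. So genes with defence names were also among those that set 0N+ABA replicate 2 apart. A 2N+ABA library under a 0N+ABA label is argued against by its high-affinity nitrate uptake median of -2.5 relative to the gene means, near -2.66 and -2.15 in its group and far below 1.68 to 3 in 2N+ABA. A weaker low-oxygen response is a candidate explanation that these values do not settle. A list of 54 genes was written after hemoglobin, alcohol dehydrogenase and early nodulin genes were seen, and without them. Its median was -0.467, against 0.33 and 0.285 in the other 0N+ABA libraries, and 39 genes lay below both. Because the genes left out had already been seen in this library, a low median was likely beforehand and adds little. Plant cysteine oxidases 4 and 5 went the other way, with medians of 0.346 and 0.343. The list median was also low in 2N+ABA replicate 3 (-0.318), so it may vary with something other than nitrate. A larger share of differentiated tissue stays open, because the endodermis median was high in this library (0.248) but the histone and cyclin median of 0.161 lay between those of the other 2, and no biological explanation from the design was tested.

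Of 108 LEA protein and dehydrin genes, 29 rose in 2N+ABA, and 1 to 6 rose without any library other than 0N+ABA replicate 2. The list passed camera at the preset correlation, but not with an estimated one or by fry (adjusted p = 0.341 and 0.0931). 0N+ABA replicate 2 alone is argued against, since its list median of -0.04 lay above those of the other 0N+ABA libraries (-0.51 and -0.46), and 67 members rose without that library against 29 with it, as calls over all genes went from 1210 to 4607. A larger share of differentiated root tissue in the 2N+ABA libraries may contribute and cannot be told apart from a change in expression, because the endodermis median log2 fold change was 0.302, below the 0.616 of the LEA list, and those of xylem and phloem were 0.0989 and 0.0233. Such a share may also contribute to the lower histone and cyclin list (median -0.31), and this was not tested apart. Nitrate, which differs between the groups, stays open as a biological explanation, and cannot be told apart from the chloride given in its place.

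More genes were higher than lower in 2N+ABA, at 74.2% of calls. 0N+ABA replicate 2 alone is argued against as the cause of the whole excess, since the share was 61.9% of 4607 calls without it. The share tended to be lower with more calls, as with 88.7% of 283 calls without 2N+ABA replicate 1. The part of 0N+ABA replicate 2 was therefore not separated from the number of calls. TMM scaling stays open, because the other scalings, with a lowest share of 71.3%, moved log2 fold changes by medians of only 0.0041 and -0.016 and so decide little. Of genes at an unadjusted p under 0.05, 52.6% were higher. The 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 1210 genes, 708 at least 2-fold and 19 lists, against a highest of 0, 0 and 14 by edgeR and camera in the other splits. The other splits held 894 to 4965 genes at an unadjusted p under 0.05. They passed 7 to 14 lists by camera at the preset correlation, so mixed groupings also gave many list calls. Each of the other splits held the groups in unequal shares. Part of the real difference thus remained between its sides, and part added to the spread within them. Neither the list calls nor the 0 genes of these splits are therefore a background without any group difference.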
